A study of Mus musculus with 18 samples.

How the data were processed

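The 18 libraries were 3′ end mRNA sequencing libraries from input and anti-GFP pulldown fractions of mouse dorsal root ganglion extracts, in 4 groups of 4 biosamples. The deposited file lists 22021 genes with 1 column per library and 2 further columns in which the authors merged the subsamples of biosample 7. Per the submitters' processing notes the reads were handled with FastQC 0.11.5, TopHat2 2.1.1, Bowtie2 2.2.9 and Cufflinks 2.2.1 on genome build GRCm38.p4, named without their order, and per the file headers the gene models were GENCODE vM10. The strand setting of the counting and any use of molecular identifiers are not stated, so overlapping genes cannot be separated here and reads are not independent molecules. The file headers name the values TPM, but the deposited values are CPM, reads scaled to the same total in every library. Each column has that total, and 98.0% to 99.0% of its non-zero values are whole multiples of 1 step per library, within a tolerance of 0.0051 CPM. They carry no division by transcript length, which 3′ end reads do not need. The comparisons were fixed with the name TPM for these values, and the same steps were applied to them as CPM. The step gives each library's reads over the listed genes, 4266007 to 14478012 in input and 5972327 to 32713515 in TRAP, and the 3-read floor of 0.0917 to 0.703 CPM. Floors cover counting error only.

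The groups follow the sample labels. Input and pulldown were taken from 1 homogenate, so libraries were paired by biosample number. The subsamples of biosample 7 were averaged per fraction into 1 replicate, which gave 16 pooled libraries, and the 2 merged columns were used only to read off the authors' weights. Genes with at least 1 CPM in at least 4 of the 16 pooled libraries were tested, 14214 of 22021; 3839 genes were at 0 in all libraries and 39 symbols occurred more than once. Values were transformed as log2(CPM + 1), so that fold changes of genes near the floor are understated.

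The 5 comparisons were tested with limma 3.58.1 in R 4.3.3 (intensity trend on, robust estimation off). TRAP against input in each treatment and the interaction came from 1 fit with biosample as a fixed block. Paclitaxel against normal was fitted on the 8 pulldowns and on the 8 inputs separately, since biosamples are nested in treatment. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, and all p-values are two-sided. Scn10a, Rpl10a and the summed CPM of 14 marker lists were also tested by exact sign flips over the 8 biosamples and by exact permutation of 4 against 4 biosamples, adjusted over 16 values.

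The gene lists, 31 with 738 genes, covered cell types of the ganglion and its surroundings, neuronal classes, the translation and mTORC1 machinery, respiration, stress, injury and signalling. Xist was not listed, and 30 lists with at least 5 tested genes were tested with camera at a correlation of 0.01, adjusted over the lists of a comparison. The test was repeated with an estimated correlation, which left 0 calls in each of the 5 comparisons, and with fry, which tests whether the genes of a list move 1 way on balance and compares them with no other genes. fry called 24, 23, 0, 3 and 0 lists, where camera called 12, 22, 1, 9 and 5. Named genes were the 8 with the largest change per comparison and direction among genes that passed, with a mean of at least 5 CPM in the higher group and no overlap between groups, filled to 4 with the lowest p where fewer passed. To these came 10 genes chosen for the study's subject, Scn10a, Rpl10a, Rraga, Mtor, Rptor, Eif4e, Eif4ebp1, Esm1, Atf3 and Calca, and up to 4 members of each list. Predicted genes and bare identifiers were counted but not named. The text gives a part of these. Rpl10a and Esm1 are described among the other observations.

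The comparisons, tests, lists, naming rule and most alternative settings were fixed before the data were examined. The exact permutation of 4 against 4 biosamples was not among the tests fixed then. Alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5 CPM in 4 libraries, median-ratio scaling, quantile normalization, removal of mitochondrially encoded and globin genes, each subsample of biosample 7 alone, no intensity trend, robust estimation, a threshold of 0.1, each biosample left out in turn, no replicate block, and the block as a random effect. Added after the data were seen were edgeR 4.0.16 (quasi-likelihood, TMM) on the recovered whole reads, the authors' weights for the subsamples, removal of each library's trend with transcript length and 3′ end GC (a spline with 4 degrees of freedom, GC over the last 500 nt), and leaving out the 4 biosamples with the fewest pulldown genes, 2 per treatment after the subsamples of biosample 7 were averaged. Coordinates, lengths and GC came from GENCODE vM21 on GRCm38, in which 14146 of the tested genes (99.5%) were found.

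The tests were tried on simulated data with the spread of these libraries. Noise was drawn for each library on its own, with no effect shared by the 2 libraries of a biosample. Counting error was added to a spread that already held it. Changes of 4-fold were recovered in 34.3% and 35.8% of genes for TRAP against input in normal and paclitaxel biosamples, 20.9% and 80.6% for paclitaxel against normal in pulldowns and inputs, and 4.48% for the interaction. Calls among genes with no simulated change numbered 1, 4, 1, 11 and 2. Only 67 of 14214 genes carried a 4-fold change in each run. For TRAP against input all simulated calls numbered 68 and 75, against 4233 and 3963 in the data. The adjusted threshold was therefore stricter in the simulation, and these recovered shares need not hold for the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.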

Results

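Translating ribosome affinity purification (TRAP) was applied to dorsal root ganglia of mice in which Cre recombinase, driven from the gene of the sodium channel Nav1.8, switched on a ribosomal protein L10a fused to GFP. Antibodies against GFP then recover ribosomes of Nav1.8-expressing sensory neurons, a population made up mostly of nociceptors, together with the mRNA bound to them. From each ganglion homogenate an input library of the whole extract and a TRAP library of the pulldown were sequenced from the 3′ ends of the transcripts. The libraries formed 4 groups of 4 biosamples each: normal input and normal TRAP (biosamples 1 to 4), and paclitaxel input and paclitaxel TRAP (biosamples 5 to 8). Paclitaxel, a microtubule-stabilising cancer drug that can cause a painful neuropathy, was given in 4 intraperitoneal injections of 4 mg/kg within 8 days, a cumulative dose of 16 mg/kg. Biosample 7 consisted of 2 subsamples, which made 18 libraries and 16 after the subsamples were averaged. Per the series text 2 of 5 assays were pooled to give 4 replicates, so the subsamples were not 1 assay sequenced again. The treatment notes describe vehicle-dosed animals, but the labels do not state whether the normal group were these. Nor do they state the number of animals per biosample or their sex.

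The normal inputs held 14373917, 12747019, 14478012 and 4266007 reads over the listed genes, and the normal TRAP libraries 20045659, 26825868, 19357218 and 5972327. The paclitaxel inputs held 9788634, 12371031, 7500805 and 6398739 (the subsamples of biosample 7) and 6536086 reads, and the paclitaxel TRAP libraries 15262869, 32713515, 10666813 and 12049105 (the subsamples) and 10576016. A value of 1 CPM, a unit of reads scaled to the same total in every library, was reached or passed by 13152 to 14043 genes in the input libraries and by 8081 to 13228 genes in the TRAP libraries. A count of 3 reads, taken as the floor, corresponded to 0.0917 to 0.703 CPM, a limit that covers counting error only. Mitochondrially encoded mRNAs made up 0.382% to 2.3% of the input reads and 0.0563% to 0.414% of the TRAP reads.

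**Figure D1:**
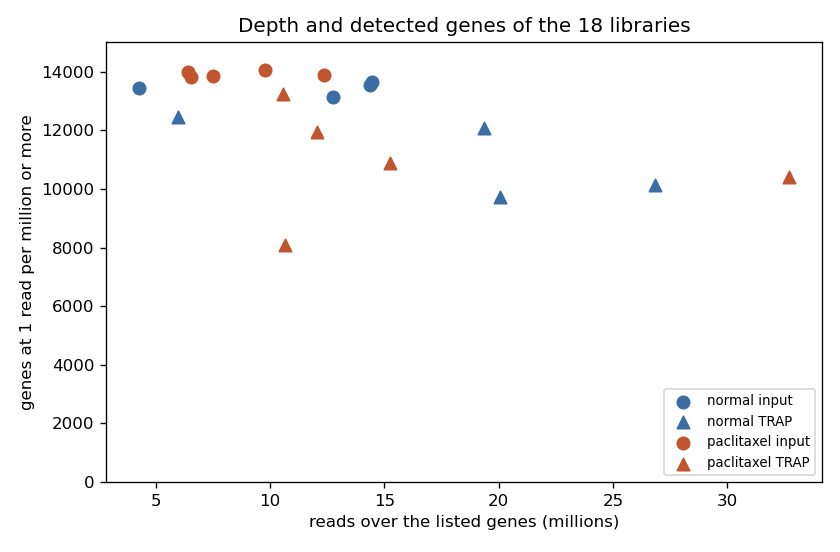
Genes at 1 CPM or more (y axis, number of genes) against reads over the listed genes (x axis, labelled in units of M reads) for the 18 libraries, with 1 point per library, circles for input and triangles for TRAP. The 9 TRAP libraries lie between 8081 and 13228 genes and the 9 input libraries between 13152 and 14043.

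The first comparison asked which mRNAs the tagged ribosomes carried relative to the whole ganglion extract of the same biosample. In the normal biosamples Scn10a, the gene of Nav1.8 (ENSMUSG00000034533.9, GRCm38 chromosome 9, 119608456 to 119719322, minus strand), had a mean of 666 ± 248 CPM in input and 1002 ± 338 CPM in TRAP (SD, n = 4), a log2 change of 0.59 (SE 0.195, limma adjusted p = 0.0267). Over the 8 biosamples of both treatments Scn10a was higher in the pulldown in 8 of 8, by a mean of 0.945 ± 0.559 on the log2 scale (SD, two-sided exact sign-flip permutation test, p = 0.00781, adjusted p = 0.00961 over 16 values). That p is the smallest that 8 pairs can give. Of 25 nociceptor markers, 5 rose, 2 fell and 18 did not pass (5 and 2 adjusted over the list alone). The list rose against all other genes (median log2 change 0.19, camera adjusted p = 5.7e-05, and 0.229 with an estimated correlation). Prph, the intermediate filament peripherin of small sensory neurons, rose by 1.33 (adjusted p = 1.43e-05) and Cysltr2, a leukotriene receptor, by 2.58 (adjusted p = 0.00312). Calca, which encodes the neuropeptide CGRP (ENSMUSG00000030669.13, chromosome 7, 114631478 to 114636357, minus strand), fell by 0.94 (SE 0.179, adjusted p = 0.000528), from 1226 ± 488 to 640 ± 252 CPM (SD, n = 4, limma). Trpv1, the capsaicin receptor, fell by 1.14 (adjusted p = 0.0237). Large-fibre and proprioceptor markers come from neurons that mostly lack Nav1.8. Of these 10 of 16 fell and 0 rose (13 and 0 adjusted over the list alone, median -1.2, adjusted p = 0.0059, and 0.241 with an estimated correlation). Etv1 fell by 2.32 and Ntrk2 by 1.59. Over both treatments, the summed shares of nociceptor and of general (pan-neuronal) markers were each higher in the pulldown in 8 of 8 biosamples. That of large-fibre markers was higher in 0 of 8 (exact sign-flip tests, adjusted p = 0.00961 for each of these shares).

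Several lists of other cell types fell in the normal pulldowns. Of 14 satellite glia markers 10 fell (13 adjusted over the list alone, camera adjusted p = 2.2e-05, and 0.229 with an estimated correlation), led by Cdh19 (-3.04) and Fabp7 (-2.99), a fatty acid binding protein of these cells. Of 18 myelinating Schwann cell markers 16 fell (16 over the list alone, adjusted p = 3.62e-07, and 0.229 with an estimated correlation), with Ugt8a, an enzyme of myelin lipid synthesis, at -3.1. Of 14 fibroblast markers 11 fell (12 over the list alone, adjusted p = 1.07e-06, and 0.229 with an estimated correlation), including the matrix genes Dcn (-2.35) and Col1a2 (-2.19). Of 21 macrophage and antigen presentation markers 9 fell (11 over the list alone, adjusted p = 0.0478, and 0.372 with an estimated correlation), including Mrc1 (-2.33). All 11 mitochondrially encoded mRNAs, which are translated on mitochondrial ribosomes, fell (11 over the list alone, median -3.1, adjusted p = 9.65e-11, and 0.229 with an estimated correlation). mt-Nd4 went from 3089 ± 996 to 249.7 ± 31.4 CPM (SD, n = 4, limma adjusted p = 2.94e-10). Of 18 immediate early genes, transcription factors and others induced within minutes of stimulation, 11 fell (11 over the list alone, adjusted p = 0.0434, and 0.229 with an estimated correlation), with Nr4a2 at -3.77. The lists of other leukocyte (4 of 6 fell, 4 over the list alone, adjusted p = 0.0643), skeletal muscle (6 of 8, 6 over the list alone, 0.0819), erythroid (3 of 7, 4 over the list alone, 0.0916), pericyte (4 of 10, 7 over the list alone, 0.149) and endothelial markers (6 of 12 fell and 1 rose, the same over the list alone, 0.343) did not pass against all other genes. Exact sign-flip tests of summed shares, over the 8 biosamples of both treatments, compare a list with no other genes. The endothelial share was higher in the pulldown in 1 biosample (sign-flip adjusted p = 0.0166), the shares of the others in 0 (0.00961 each). The satellite glia, Schwann, fibroblast, macrophage and mitochondrially encoded shares were also higher in 0 (sign-flip adjusted p = 0.00961 each).

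The ribosomal protein and translation factor lists rose against all other genes in the normal pulldowns, and some of their genes passed. Of 79 cytosolic ribosomal protein genes 37 rose and 4 fell (38 and 4 adjusted over the list alone; median 0.52, camera adjusted p = 1.84e-28, and 0.229 with an estimated correlation), including Rpl24 (1.87) and Rpl14 (1.85). Of 46 translation initiation and elongation factors 12 rose and 6 fell (16 and 7 over the list alone, adjusted p = 2.12e-07, and 0.229 with an estimated correlation), with Eif3m at 2.37 and Eif4g3 at -1.54. Of 38 tubulin and microtubule-associated genes 9 rose and 5 fell (9 and 6 over the list alone, adjusted p = 2.2e-05, and 0.229 with an estimated correlation), with the axonal motor Kif5a at 1.89 and Map2 at -1.79. Of 76 nuclear-encoded oxidative phosphorylation genes 22 rose and 14 fell (23 and 19 over the list alone). The list test was upward (adjusted p = 1.07e-06, and 0.315 with an estimated correlation) with a mean of 0.038 and a median of -0.02. Ndufs5 of complex I rose by 2.08 and Sdhb of complex II fell by 2.06. Of 44 genes of the mTORC1 and Rag-Ragulator pathway 3 rose and 8 fell (3 and 5 over the list alone, adjusted p = 0.622). The series title names this pathway, so the list is not independent of these samples, and the test pointed upward while the median was -0.49. The largest increases were in Serpina11, a serpin (3.4), the proteasome subunit gene Psmb3 (2.89, from 185 ± 44.7 to 1506 ± 745 CPM, SD, n = 4) and Timmdc1, an assembly factor of complex I (2.79). The largest decreases included Akap2 (-3.82) and Gabrg1, a GABA receptor subunit (-3.72). Akap2 overlaps on its strand with Pakap, which rose by 2.55.

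Of 14214 genes tested in normal biosamples with limma, 4233 passed, 724 higher and 3509 lower in TRAP. In 6371 genes, 44.8% of those tested, all 4 biosamples differed in 1 direction, against 12.5% by chance for differences centred on 0. The differences were not so centred (median of all genes -0.66), so the excess cannot be read as a share of changed genes. With an estimated correlation 0 of the 12 list calls held, and with fry the nociceptor (adjusted p = 0.209), oxidative phosphorylation (0.464) and tubulin (0.232) lists did not pass. The median log2 change of all genes was -0.66. Median-ratio scaling, quantile normalization and edgeR moved it by 0.33, 0.66 and 0.21 and the higher share of passing genes from 17.1% to 45.1%, 48.5% and 67.2%. Here and in the later comparisons the edgeR changes lack the added 1 of log2(CPM + 1), so that shift mixes scaling with the pseudocount. Pseudocounts of 0.1 and 5 alone moved the median here by -0.29 and 0.31. The falls of Calca and Trpv1 no longer passed under median-ratio scaling (log2 change -0.499 and -0.719). The rise of Scn10a (0.457) and the tubulin list (adjusted p = 0.404) no longer passed under quantile normalization. The macrophage list no longer passed under quantile normalization (adjusted p = 0.133), with a pseudocount of 5 (0.0685), with a filter of 5 CPM (0.0535), or without biosamples 1, 3 or 4 (0.0674, 0.166 and 0.122). The immediate early list no longer passed with a pseudocount of 0.1 (adjusted p = 0.0641) or without biosamples 1, 3 or 4 (0.0656, 0.0926 and 0.0708). The count was 2319 without biosample 1, 1864 by edgeR and 2430 without the 4 biosamples whose pulldowns reached 1 CPM in the fewest genes, 2 per treatment with the subsamples of biosample 7 averaged (biosamples 1, 2, 5 and 6).

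**Figure D2:**
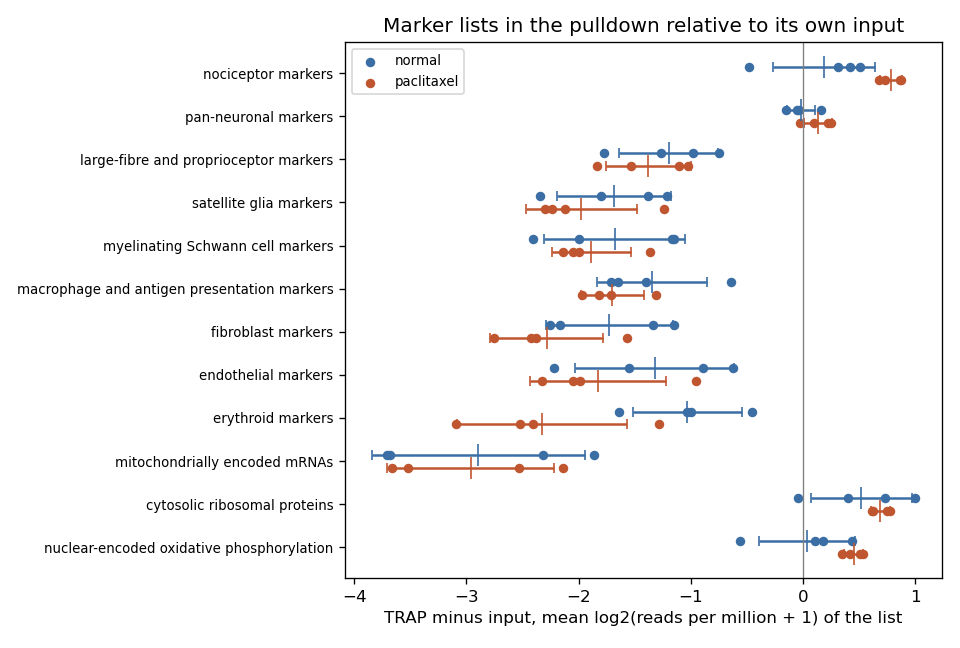
Difference between TRAP and input in the mean log2(CPM + 1) of each list (x axis), with 1 point per biosample, a vertical tick for the mean and a bar for 1 SD (n = 4 per treatment). The 11 mitochondrially encoded mRNAs have a median change of -3.1 in normal and -2.9 in paclitaxel biosamples, and the 79 ribosomal protein genes 0.52 and 0.77.

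The same comparison within the paclitaxel biosamples asked what the tagged ribosomes carried after treatment. Scn10a had 562.3 ± 76.4 CPM in input and 1405 ± 297 CPM in TRAP (SD, n = 4), a log2 change of 1.3 (SE 0.195, limma adjusted p = 6.81e-05). Of 25 nociceptor markers 14 rose and 1 fell (15 and 1 adjusted over the list alone; median 0.79, camera adjusted p = 6.15e-17, and 0.0866 with an estimated correlation). Mrgprd, a receptor of nonpeptidergic nociceptors, rose by 1.96, Tmem233 by 1.6, and Calca by 0.785 (SE 0.179, adjusted p = 0.0031). Of 16 pan-neuronal markers 4 rose and 3 fell (6 and 4 over the list alone, adjusted p = 0.0055, and 0.0936 with an estimated correlation), with Uchl1 at 1.41 and Map2 at -1.24. Of 16 large-fibre and proprioceptor markers 12 fell (13 over the list alone, adjusted p = 0.000396, and 0.0977 with an estimated correlation), including Runx3 (-2.67).

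Of the markers of other cells in the paclitaxel pulldowns, 12 of 14 satellite glia markers fell (14 adjusted over the list alone, camera adjusted p = 1.4e-07, and 0.0902 with an estimated correlation), including the gap junction gene Gja1 (-3.52). Falls were also recorded in 16 of 18 Schwann cell markers (16 over the list alone, adjusted p = 3.87e-10, and 0.0866 with an estimated correlation; Gldn -3.29), 13 of 21 macrophage markers (13 over the list alone, adjusted p = 0.000298, and 0.0936 with an estimated correlation; Cd163 -3.25) and 12 of 14 fibroblast markers (13 over the list alone, adjusted p = 4.6e-11, and 0.0866 with an estimated correlation; Col1a1 -2.68). Falls were recorded in 7 of 7 erythroid markers (7 over the list alone, adjusted p = 5.88e-06, and 0.0866 with an estimated correlation; Hba-a1 -3.62), 8 of 12 endothelial markers (10 over the list alone, adjusted p = 0.0169, and 0.171 with an estimated correlation; Cdh5 -3.47) and 6 of 8 skeletal muscle markers (6 over the list alone, adjusted p = 0.000119, and 0.0936 with an estimated correlation; Mylpf -3.69). Falls were recorded in 4 of 6 other leukocyte markers (5 over the list alone, adjusted p = 0.00535, and 0.0866 with an estimated correlation; S100a9 -2.04), 5 of 10 pericyte and smooth muscle markers (7 over the list alone, adjusted p = 0.0467, and 0.29 with an estimated correlation; Tagln -2.48) and 9 of 14 cytokines and chemokines (12 over the list alone, adjusted p = 0.00535, and 0.155 with an estimated correlation; Il33 -3.22). All 11 mitochondrially encoded mRNAs fell (11 over the list alone, median -2.9, adjusted p = 2.99e-12, and 0.0866 with an estimated correlation), and 13 of 18 immediate early genes fell (14 over the list alone, adjusted p = 0.00281, and 0.0866 with an estimated correlation; Fos -2.75).

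Ribosomal protein genes rose in 44 of 79 cases and fell in 0 in the paclitaxel pulldowns (46 and 0 adjusted over the list alone; median 0.77, camera adjusted p = 1.75e-35, and 0.0866 with an estimated correlation). Oxidative phosphorylation genes rose in 32 of 76 cases and fell in 1 (34 and 2 over the list alone; median 0.59, adjusted p = 1.47e-20, and 0.0866 with an estimated correlation), with Ndufv3 of complex I at 1.89. Tubulin and microtubule-associated genes rose in 11 of 38 cases and fell in 4 (12 and 4 over the list alone, adjusted p = 2.7e-07, and 0.0866 with an estimated correlation), with the beta-tubulins Tubb2a at 1.6 and Tubb4b at 1.46, and 9 of 46 translation factors rose and 3 fell (9 and 3 over the list alone, adjusted p = 2.04e-06, and 0.0866 with an estimated correlation; Eif3k 1.47). Among 55 pain-related ion channels 11 rose and 10 fell (11 and 10 over the list alone), with Kcnd2 falling by 2.21. The camera test was upward (adjusted p = 0.00255, and 0.0936 with an estimated correlation) while the median was -0.097 and the mean -0.13. Of 44 mTORC1 pathway genes 2 rose and 5 fell (1 and 4 over the list alone, adjusted p = 0.168, test upward and median -0.16). That list is not independent of these samples. Rnasek and Nmb, the gene of the neuropeptide neuromedin B, each overlap another gene on their strand. Rnasek rose by 3.78, and Nmb rose from 359 ± 67.4 to 1577 ± 63.5 CPM (SD, n = 4, log2 change 2.15). Bhlhe40, a transcriptional repressor, fell by 4.37.

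In 48.0% of the genes tested in paclitaxel biosamples all 4 differed in 1 direction, against 12.5% by chance for differences centred on 0. The differences were not so centred (median of all genes -0.56), so the excess cannot be read as a share of changed genes. Of 14214 genes tested with limma, 3963 passed, 699 higher and 3264 lower in TRAP. Of these, 356 were higher and 1648 lower in both treatments (35.6 and 806 if the calls were independent), and 14 passed in opposite directions. The calls were not independent, since both comparisons used 1 spread per gene from the same fit and both medians were below 0. The excess over those numbers is therefore no measure of agreement between the treatments. With an estimated correlation 0 of the 22 list calls held, and with fry the pan-neuronal (adjusted p = 0.128), translation factor (0.0975), tubulin (0.0527), ion channel (0.837), heat shock (0.372) and cholesterol (0.614) lists did not pass. Median-ratio scaling, quantile normalization and edgeR moved the median change of all genes from -0.56 by 0.27, 0.60 and 0.20 and the higher share of passing genes from 17.6% to 39.3%, 47.6% and 59.9%. Quantile normalization ended the calls of the pan-neuronal (adjusted p = 0.85), tubulin (0.121), ion channel (0.111), pericyte (0.088), heat shock (0.673) and cholesterol (0.686) lists. The pericyte list also lost its call in 9 other settings, among them leaving out biosamples 2, 4, 5, 6 or 8 (adjusted p = 0.0536, 0.0503, 0.0896, 0.0508 and 0.0547). The count was 2121, 2039 and 2488 without biosamples 5, 6 and 7, 1915 by edgeR, and 1871 without the 4 biosamples with the fewest pulldown genes.

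The comparison of paclitaxel with normal pulldowns asked which ribosome-bound mRNAs of Nav1.8 neurons differed after treatment. Of 76 nuclear-encoded oxidative phosphorylation genes 15 rose and 0 fell (37 and 3 adjusted over the list alone; median log2 change 0.91, camera adjusted p = 3.09e-08, and adjusted p = 0.951 with an estimated correlation). The fry test of this list gave adjusted p = 0.0603. Sdhb of complex II went from 10.2 ± 13.3 to 98.1 ± 59.6 CPM (SD, n = 4; log2 change 3.7, SE 0.761, limma adjusted p = 0.0276), and Ndufs8 of complex I rose by 2.76, Cox7b of complex IV by 2.64 and Ndufa4 by 2.44. The share of mitochondrially encoded mRNAs differed by 1.43 in the same pulldowns (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 can give, adjusted p = 0.153). Of these mRNAs mt-Nd2 (2.73) and mt-Nd1 (1.64) rose, 2 of 11 (5 over the list alone, camera adjusted p = 0.11). Their share was 0.312% and 0.414% in the pulldowns of biosamples 7 and 8 but 0.0986% and 0.103% in those of 5 and 6, near the normal maximum of 0.0861%. The inputs of biosamples 7 and 8 (2.17% and 1.9%) also stood above those of 5 and 6 (1.09% and 1.01%). Of 25 nociceptor markers 3 rose and 0 fell (7 and 2 over the list alone, adjusted p = 0.103), including Calca, from 640 ± 252 to 2123 ± 580.2 CPM (SD, n = 4; log2 change 1.78, SE 0.315, limma adjusted p = 0.0146), and Calcb, a second CGRP gene (1.6). Scn10a had a log2 change of 0.53 (SE 0.303, adjusted p = 0.41).

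Rraga, the gene of the RagA GTPase that recruits mTORC1 to lysosomes (ENSMUSG00000070934.6, chromosome 4, 86575668 to 86577285, plus strand), rose from 89.3 ± 50.8 to 342 ± 101 CPM in the pulldowns (SD, n = 4; log2 change 2.17, SE 0.471, limma adjusted p = 0.034). Lamtor5, of the Ragulator complex, rose by 1.98, and Akt1s1, the gene of the mTORC1 inhibitor PRAS40, fell by 2.51 (SE 0.35, adjusted p = 0.00889). Another gene overlaps Akt1s1 on its strand. These made 2 rises and 1 fall among 44 pathway genes (2 and 2 adjusted over the list alone, camera adjusted p = 0.977), a list not independent of these samples. Mtor (1.97, adjusted p = 0.23), Rptor (0.045, adjusted p = 0.986), Eif4e (0.26, adjusted p = 0.716) and Eif4ebp1 (1.65, adjusted p = 0.399) did not pass. Of 79 ribosomal protein genes 7 rose and 2 fell (20 and 8 over the list alone, adjusted p = 0.11), with Rps29 at 2.88 and Rpl39 at 2.29. Tubb4b (2.16), Tubb2a (1.8) and Tubb5 (1.5), which encode beta-tubulins, the protein paclitaxel binds, rose, 3 of 38 microtubule genes (7 and 2 over the list alone, adjusted p = 0.447). Nefm, a neurofilament gene, fell by 1.41 and Thy1 rose by 1.57 among 16 pan-neuronal markers (1 and 1 over the list alone, adjusted p = 0.856). The summed share of these markers differed by -0.816 (two-sided exact permutation p = 0.0286, adjusted p = 0.153), from 2.66% to 4.75% in normal and 1.61% to 2.4% in paclitaxel pulldowns. Of 22 nerve injury response genes 0 passed (1 over the list alone, adjusted p = 0.603), among them Atf3 (-0.605, adjusted p = 0.835) and Gap43 (0.45, adjusted p = 0.335).

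Among the largest differences in the pulldowns, Gpx4, a selenoenzyme that reduces lipid peroxides (ENSMUSG00000075706.10, chromosome 10, 80047166 to 80056439, plus strand), fell from 1624 ± 486 to 314 ± 40.9 CPM (SD, n = 4; log2 change -2.32, SE 0.273, limma adjusted p = 0.00782). Slc7a5, a subunit of an amino acid exchanger, fell by 2.03, while Slc3a2, the other subunit of the same exchanger, rose by 2.82. Bhlhe40 fell by 4.01, the chaperonin subunit gene Cct8 by 2.37 and Phc2, of a Polycomb complex, by 2.16. Fam43b rose by 4.09 and Esyt1, which tethers the endoplasmic reticulum to the plasma membrane, by 3.57. With limma, 259 of 14214 genes passed, 189 higher and 70 lower, and 1465 genes (10.3%) had no overlap between the groups, against a chance average of 2.86%. Genes move together, so 1 grouping can exceed that average, and the excess cannot be read as a share of changed genes. At an unadjusted p under 0.05 with limma, other groupings of the pulldowns reached up to 1582 genes, where 711 were expected. The limma count was 0 without biosample 2 or without biosample 8 (2058 and 2037 genes at an unadjusted p under 0.05). It was 70, 543, 135, 128 and 13 without biosamples 1, 3, 4, 5 and 7, 0 with no filter or no intensity trend (2372 and 2148 genes unadjusted), 1 without the 4 biosamples with the fewest pulldown genes, and 478 by edgeR. Higher counts came with a filter of 5 CPM (729) and robust estimation (590). With a spread shared with the inputs the count was 1660 with no replicate block and 1685 with a random block. Median-ratio scaling, quantile normalization and edgeR moved the median change of all genes from 0.17 by -0.16, -0.18 and -0.19, the higher share of passing genes from 73.0% to 46.4%, 59.2% and 40.4%. Rraga did not pass under median-ratio scaling (log2 change 1.95, adjusted p = 0.0516).

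**Figure D3:**
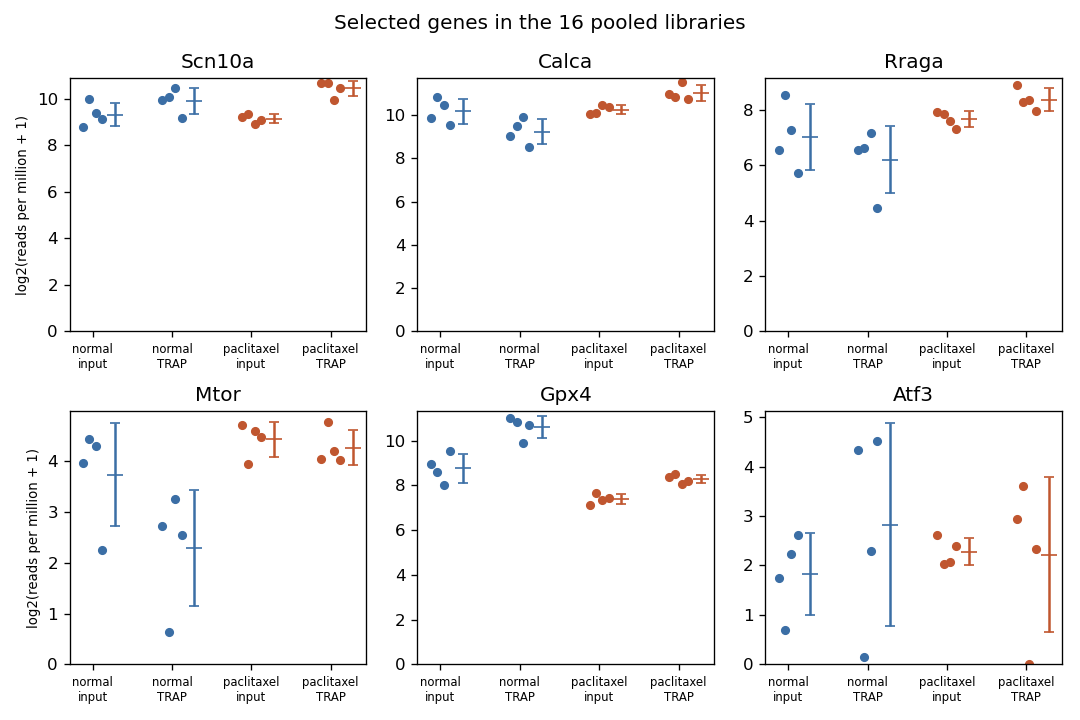
log2(CPM + 1) of Scn10a, Calca, Rraga, Mtor, Gpx4 and Atf3 (y axes) in the 4 groups (x axes), with 1 point per biosample, a horizontal tick for the mean and a bar for 1 SD (n = 4). Mean Gpx4 was 1624 CPM in normal and 314 CPM in paclitaxel TRAP, and mean Rraga 89.3 and 342 CPM.

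The comparison of paclitaxel with normal inputs asked how the whole ganglion extract differed. Several blood and stromal lists rose against all other genes, with few of their genes passing. Hba-a1, an alpha-globin gene (ENSMUSG00000069919.7, chromosome 11, 32283511 to 32284465, plus strand), went from 29.6 ± 11.1 to 177 ± 69.6 CPM (SD, n = 4; log2 change 2.51, SE 0.298, limma adjusted p = 0.00616), and Hbb-bs, a beta-globin gene, from 144 ± 50.0 to 851 ± 476 CPM (2.45, adjusted p = 0.00841). They were the 2 of 7 erythroid markers that rose (5 adjusted over the list alone; median 0.86, camera adjusted p = 0.000498, and adjusted p = 0.414 with an estimated correlation). Of 21 macrophage markers 1 rose (9 over the list alone; median 0.70, adjusted p = 0.000201, and adjusted p = 0.731 with an estimated correlation), the lysozyme gene Lyz2 (1.63). Of 6 other leukocyte markers 3 rose (4 over the list alone; median 1.1, adjusted p = 0.00837, and adjusted p = 0.414 with an estimated correlation), S100a8 of neutrophils (1.5), Ms4a1 of B cells (1.28) and Cma1 of mast cells (1.24). Under median-ratio scaling Ms4a1 (1.18, adjusted p = 0.066) and Cma1 (1.11, 0.0527) did not pass. Of 14 fibroblast markers 1 rose (8 over the list alone; median 0.94, adjusted p = 0.000201, and adjusted p = 0.637 with an estimated correlation), Apod (1.79), and of 14 satellite glia markers 2 rose (5 over the list alone, adjusted p = 0.0212, and adjusted p = 0.793 with an estimated correlation), Fabp7 (1.99) and Slc1a3 (1.69). Of 14 cytokines and chemokines 1 rose (4 over the list alone, adjusted p = 0.0147, and adjusted p = 0.414 with an estimated correlation), Il18 (1.5), whereas 0 of 18 Schwann cell markers passed (0 over the list alone, adjusted p = 0.382). The endothelial (1 of 12 rose, 1 over the list alone) and pericyte (0 of 10, 2 over the list alone) lists did not pass (adjusted p = 0.314 each).

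The pan-neuronal and nociceptor lists moved the other way in the inputs, but the large-fibre and proprioceptor list did not. Of 16 large-fibre markers 12 had positive changes and 0 passed (4 higher adjusted over the list alone, median 0.51, camera adjusted p = 0.0873). Of 16 pan-neuronal markers 1 fell (2 adjusted over the list alone; median -0.20, camera adjusted p = 0.00803, and adjusted p = 0.414 with an estimated correlation), Uchl1, an abundant neuronal deubiquitinase, from 6021 ± 1204 to 2715 ± 473 CPM (SD, n = 4; log2 change -1.14, limma adjusted p = 0.0482). Of 25 nociceptor markers 0 passed (3 lower over the list alone; median -0.18, adjusted p = 0.01, and adjusted p = 0.731 with an estimated correlation), among them Scn10a (-0.185, SE 0.252, adjusted p = 0.731) and Prph (-0.57, adjusted p = 0.245). Calca differed by 0.057 (adjusted p = 0.935), or by -0.0461 under median-ratio scaling. The summed share of pan-neuronal markers differed by -0.446, of macrophage markers by 0.586, of other leukocyte markers by 1.22, of erythroid markers by 1.24 and of endothelial markers by 0.283 on the log2 scale (two-sided exact permutation tests, p = 0.0286 each, the smallest that 4 against 4 can give, adjusted p = 0.0915 over 16 values). Of 11 mitochondrially encoded mRNAs 3 rose (7 and 1 lower over the list alone; median 0.98, camera adjusted p = 0.00803, and adjusted p = 0.792 with an estimated correlation), mt-Nd2 (2.24), mt-Atp8 (2.13) and mt-Cytb (1.85), the last not under median-ratio scaling (adjusted p = 0.0627). Akt1s1 fell by 1.22 (SE 0.274, adjusted p = 0.042), the 1 of 44 mTORC1 pathway genes that passed (2 higher and 1 lower over the list alone, adjusted p = 0.546, test downward and median 0.066). That list is not independent of these samples, and Rraga had 0.66 (adjusted p = 0.426). Of 76 oxidative phosphorylation genes 2 rose in the inputs (3 over the list alone, median 0.43, adjusted p = 0.0507).

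The largest increases in the inputs included Loxl2, a collagen crosslinking enzyme (2.59), Ptcra, the pre-T cell receptor alpha chain (2.38), and Psmb11, a proteasome subunit of the thymus (2.32). The largest decreases were Gpx4 (-1.38, SE 0.278, limma adjusted p = 0.0268), the GTPase gene Drg2 (-1.33), Nup88 of the nuclear pore (-1.31) and the selenoprotein gene Sepw1 (-1.2). With limma, 233 of 14214 genes passed, 207 higher and 26 lower, and 1607 genes (11.3%) had no overlap between the groups, against a chance average of 2.86%. That excess cannot be read as a share of changed genes either. Other groupings of the inputs reached up to 2209 genes at an unadjusted p under 0.05 with limma, where 711 were expected. Of the genes called in the pulldowns and in the inputs, 9 were higher in both, 5 lower in both and 0 opposite, in fractions of the same biosamples. The median change of all genes moved from 0.14 by -0.093, -0.17 and -0.16 under median-ratio scaling, quantile normalization and edgeR, and the higher share from 88.8% to 75.8%, 78.2% and 68.1%. The limma count was 0 without biosample 1 or with no filter (2065 and 2962 genes at an unadjusted p under 0.05). It was 827, 391, 128, 21, 7 and 18 without biosamples 2, 3, 4, 5, 7 and 8. It was 1 with a spread shared with the pulldowns, 144 by edgeR and 118 without the 4 biosamples with the fewest pulldown genes. Leaving out biosample 2 ended the calls of the nociceptor and satellite glia lists (adjusted p = 0.43 each) and the mitochondrially encoded list (0.059), the last also lost without biosample 4 (0.137). The other leukocyte list lost its call without biosample 8 (adjusted p = 0.0995) and with no filter (0.187), and the cytokine list without biosample 3 (0.0511). Quantile normalization ended the pan-neuronal (adjusted p = 0.243) and nociceptor (0.0925) calls, and leaving out the 4 biosamples with the fewest pulldown genes the nociceptor (0.761) and satellite glia (0.501) calls. With fry the erythroid, other leukocyte and cytokine lists passed (adjusted p = 0.0209 each) and the other 6 did not.

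**Figure D4:**
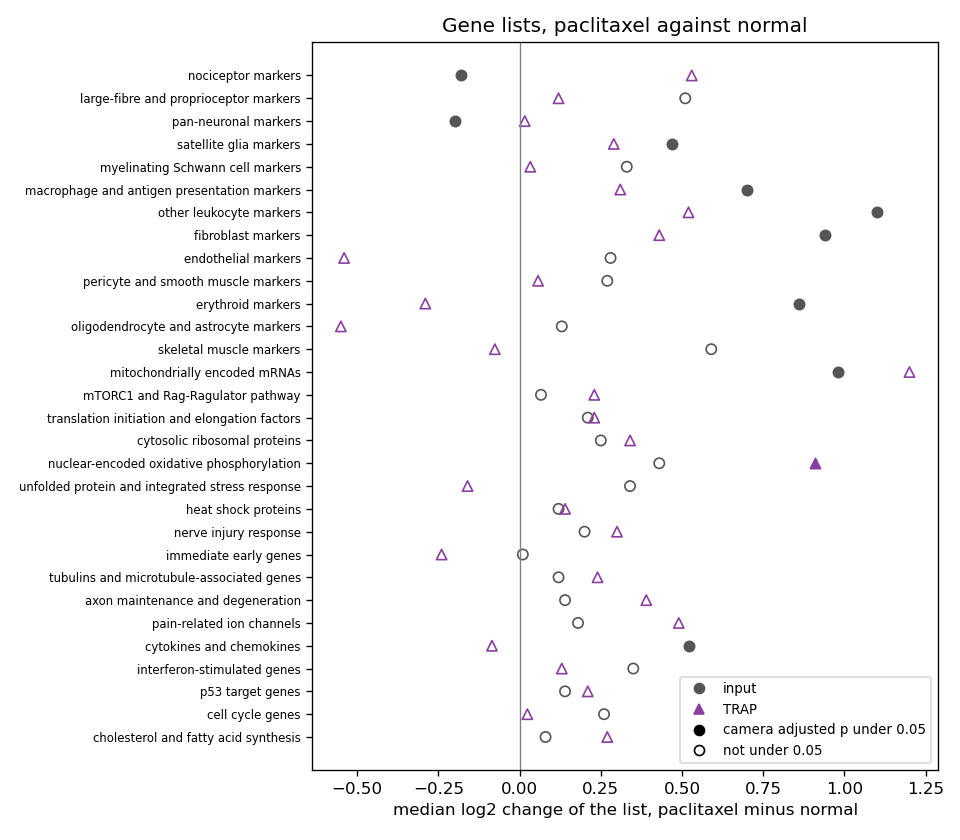
Median log2 change of each list, paclitaxel minus normal (x axis), in inputs (circles) and pulldowns (triangles), filled where the camera adjusted p was under 0.05. In the inputs 9 of 30 lists passed and in the pulldowns 1, oxidative phosphorylation at 0.91.

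The last comparison asked whether the pulldown, relative to its own input, differed between the treatments, as an interaction of paclitaxel and fraction. Calca had an interaction of 1.72 (SE 0.253, limma adjusted p = 0.0066): its pulldown was below its input in normal biosamples (640 ± 252 against 1226 ± 488 CPM, SD, n = 4) and above it in paclitaxel biosamples (2123 ± 580.2 against 1211 ± 177 CPM). It was the 1 of 25 nociceptor markers that passed (9 higher and 1 lower adjusted over the list alone), and the list rose (median 0.84, camera adjusted p = 3.63e-05, and adjusted p = 0.665 with an estimated correlation). Scn10a had an interaction of 0.716 (SE 0.275, adjusted p = 0.31) and Rraga 1.51 (SE 0.365, adjusted p = 0.0752), neither of which passed. Of 44 mTORC1 pathway genes 0 passed (2 over the list alone, adjusted p = 0.507), a list not independent of these samples. Ndufb6 had an adjusted p = 0.058 under median-ratio scaling. It and Ndufa4, at 1.55 and 1.81, were the 2 of 76 oxidative phosphorylation genes that rose (13 and 1 lower over the list alone; median 0.38, adjusted p = 0.000331, and adjusted p = 0.69 with an estimated correlation). Hagh, a glyoxalase (ENSMUSG00000024158.17, chromosome 17, 24840143 to 24864450, plus strand), had the largest interaction (2.61, SE 0.451, adjusted p = 0.0139). It had 58.2 ± 54.4 and 12.3 ± 9.92 CPM in normal input and TRAP and 68.2 ± 26.6 and 108 ± 45.4 CPM in paclitaxel input and TRAP (SD, n = 4). Slc25a3, the mitochondrial phosphate carrier, had 2.00, and Actg1, gamma-actin, 1.87, while Nefm (-1.21), the cytoskeletal linker Plec (-1.28), Anp32b (-1.37) and Nyap1 (-1.41) were the 4 genes lower.

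The erythroid list had a median interaction of -1.1 (0 of 7 passed, 2 lower adjusted over the list alone, camera adjusted p = 0.000296, and adjusted p = 0.665 with an estimated correlation). The skeletal muscle list had -0.58 (0 of 8 passed, 1 lower over the list alone, adjusted p = 0.0101, and adjusted p = 0.665 with an estimated correlation) and the fibroblast list -0.47 (0 of 14 passed, 0 over the list alone, adjusted p = 0.0172, and adjusted p = 0.69 with an estimated correlation). With limma, 27 of 14214 genes passed, 23 higher and 4 lower, and 938 genes (6.6%) had no overlap between the treatments, against a chance average of 2.86%. That excess, too, cannot be read as a share of changed genes. Other groupings reached up to 1400 genes at an unadjusted p under 0.05 with limma, where 711 were expected. The limma count was 0 without biosample 7 (1280 genes at an unadjusted p under 0.05) and 7, 87, 42, 3, 4 and 11 without biosamples 2, 3, 4, 5, 6 and 8. With no filter, no intensity trend, no replicate block or a random block it was 0, and under quantile normalization 6. It was 11 without the 4 biosamples with the fewest pulldown genes, and 0 by edgeR (1203 genes unadjusted), by which Calca had 1.59 (adjusted p = 0.1). The oxidative phosphorylation list lost its call without biosample 2 (adjusted p = 0.124) and with the length and GC trend removed (0.0652). The fibroblast list lost it without biosamples 2 or 4 (adjusted p = 0.13 and 0.231) and with no filter (0.0524), and the skeletal muscle list without biosamples 2 or 5 (0.0962 and 0.0552). Without the 4 biosamples the erythroid, skeletal muscle and fibroblast lists had adjusted p = 0.137 each, and with fry 0 of the 5 lists passed.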

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

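The tests below of oxidative phosphorylation against the input, of non-neuronal markers and of Calca carryover were chosen only after the results were seen. Removal of the length and GC trend was added after the data were seen. The tests of other groupings of the samples were chosen before.

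Single libraries stood apart from the other 3 of their group in 23 of 452 groups examined, where chance alone gives about 23. The distance of the farthest library to its nearest neighbour, as a share of the range of the group, was 0.864 for Esm1, 0.88 for A3galt2 and 0.865 for Loxl2 in normal inputs. In normal pulldowns it was 0.9245 for Cnot3, 0.88 for Esyt1 and 0.86 for Ptcra. In paclitaxel inputs it was 0.958 for Fam89a and 0.867 for Prkx. In paclitaxel pulldowns it was 0.861 for Esm1, 0.904 for Smug1, 0.895 for Mboat1, 0.927 for Fgl2, 0.881 for Phc2, 0.915 for Tmem50b and 1 for Hyal1, which was above 0 in a single library. Among list means it was 0.927 and 0.836 for erythroid markers and 0.871 and 0.927 for cell cycle genes in normal and paclitaxel inputs, 0.922 for ion channels in normal inputs, 0.8292 for pan-neuronal markers and 0.86 for tubulins in normal pulldowns, and 0.96 for satellite glia markers in paclitaxel pulldowns.

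The change of the pulldown relative to its input differed between treatments, by the interaction test, in 27 genes. The named ones were Hagh (2.61), Tmem50b (2.53), Cisd2 (2.42), Prkx (2.18), Fam177a (2.14), Slc25a3 (2), Actg1 (1.87), Ndufa4 (1.81), Calca (1.72), Nefm (-1.21), Plec (-1.28), Anp32b (-1.37) and Nyap1 (-1.41), on the log2 scale. It also differed for the nociceptor (median 0.84), oxidative phosphorylation (0.38), fibroblast (-0.47), skeletal muscle (-0.58) and erythroid (-1.1) lists, none of which passed with an estimated correlation.

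The 5 counts were set against other groupings of the same samples. For paclitaxel against normal, 1 of 35 groupings, the real one, reached the real count in the pulldowns (259), the inputs (233) and the interaction (27). The highest other count was 0 in each. That share, 0.029, is the smallest that 35 groupings can give. It is under 0.05 for each count taken alone and was not adjusted over the 5 counts. The interaction count was 0 by edgeR and without biosample 7. At an unadjusted p under 0.05 with limma the real groupings gave 2400, 2720 and 1611 genes and the highest others 1582, 2209 and 1400. For TRAP against input, flipping fractions within 4 biosamples makes 8 groupings, too few for a share under 0.05; the real counts were 4233 and 3963, reached by 1 grouping each, and the highest others 0 and 0 (6076 and 5736 unadjusted, highest others 1876 and 2207).

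Oxidative phosphorylation transcripts were higher in paclitaxel than in normal pulldowns (median 0.91). After each library's trend with transcript length and 3′ end GC was removed the median was 0.66. A bootstrap over the member genes gave a lower bound of 0.37, so that such a trend cannot be told apart as a part of the difference. That bound treats the genes as independent and holds no spread between biosamples. The list then had a camera adjusted p = 0.00243. Before the removal it had a camera adjusted p = 0.951 with an estimated correlation and 0.0603 with fry. Whether the difference was already present in the inputs stays open as well, since the pulldown minus input of the list mean differed between treatments by 0.412 with a two-sided exact permutation p = 0.0857 (n = 4 per treatment). An effect of paclitaxel on Nav1.8 neurons may account for it and stays among the open explanations.

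The erythroid, macrophage, other leukocyte, fibroblast and satellite glia lists were higher in paclitaxel inputs by camera, and none passed with an estimated correlation (adjusted p = 0.414 to 0.793). Blood left in the tissue as the whole source would not raise fibroblast markers. Their list mean was higher by 0.797 (two-sided exact permutation p = 0.0286, the smallest 4 against 4 can give). Their summed share, planned only for TRAP against input, was higher by 0.652 (exact permutation p = 0.0857, adjusted p = 0.171), so that blood cannot be told apart. A lower share of neurons would raise all other markers alike. Against Schwann cell markers, the fibroblast list mean differed between treatments by 0.587 (exact permutation p = 0.0571) and the erythroid one by 0.917 (p = 0.0286), the latter the only 1 of 9 lists tried at that p; by summed share erythroid (1.2), other leukocyte (1.18) and fibroblast (0.616) markers were at p = 0.0286. Adjusted over the 9 lists the lowest exact permutation p was 0.171 by list mean and 0.0857 by summed share, and a joint test of all 10 lists gave p = 0.343 and 0.114, so that a lower neuron share cannot be told apart. An effect of paclitaxel on the cells of the ganglion may account for it and was not tested separately.

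Calca was below its input in normal pulldowns and above it in paclitaxel pulldowns. A trend of the libraries with length and GC as the whole source is argued against, since the interaction was 1.51 (SE 0.23, limma adjusted p = 0.00882) after its removal, against 1.72 before. Unbound input RNA carried into the normal pulldowns is argued against as the whole source only as far as Calca lay below its input there. Input mixed in at any share can lower a pulldown towards its input but not below it. The outcome was therefore settled once the 2 directions were seen. Even the least depleted median of 10 lists of non-neuronal cell types, that of skeletal muscle markers, limits the input share to 0.456 (0.617 under median-ratio scaling). That share would leave the log2 change of Calca at 0.248 or above (0.314). Both values take the measured paclitaxel change of Calca less 2 SE for a normal pulldown free of input. They lie above 0 by construction and add no separate evidence. The measured change was -0.939 (SE 0.179), -0.499 (SE 0.197, limma adjusted p = 0.0699) under median-ratio scaling and -0.423 (adjusted p = 0.213) by edgeR. The fall did not pass in the last 2. An effect of paclitaxel on the ribosome loading or level of Calca in Nav1.8 neurons may account for the pattern and stays open.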

How the results depend on the processing

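The edgeR test and the runs without the 4 biosamples with the fewest pulldown genes, with the authors' weights and with the length and GC trend removed were chosen after the data were seen; all others were fixed before. Over the 5 counts 71 alternatives gave a count within 1.5 times of the first, 46 a lower and 13 a higher one. For named genes 6085 values kept their side of the threshold, 874 lost the call, 22 gained it and 1 reversed. For lists these were 1097, 119, 0 and 1. A reversal was counted only where the first or the alternative value passed. Changes of sign between values that did not pass are among the 6085. Rpl10a in TRAP against input of normal biosamples, for example, went from -0.449 to 0.527 under quantile normalization. Tubb6 in TRAP against input of paclitaxel biosamples reversed to 0.0653 under quantile normalization, and the ion channel list in the same comparison reversed under fry (adjusted p = 0.837). The counts below are in the order TRAP against input in normal and paclitaxel biosamples, paclitaxel against normal in pulldowns and inputs, and interaction, named where only some changed. Leaving out 1 biosample at a time gave 2319 to 4347, 2039 to 4360, 0 to 543, 0 to 827 and 0 to 87 genes, on fewer samples. edgeR gave 1864, 1915, 478, 144 and 0. Without the 4 biosamples with the fewest pulldown genes, on fewer samples, the counts were 2430, 1871, 1, 118 and 11. No filter, which tests 18182 genes, gave 0 in pulldowns, inputs and interaction (2372, 2962 and 1737 at an unadjusted p under 0.05 with limma), and a filter of 5 CPM 729 in pulldowns. No intensity trend gave 0 in pulldowns and interaction (2148 and 1288 unadjusted, limma). No replicate block, which shares 1 spread between fractions, gave 1660 in pulldowns, 1 in inputs and 0 for the interaction (1082 unadjusted), and a random block 1685, 1 and 0 (1497 unadjusted). Quantile normalization gave 2695 in normal biosamples, 147 in inputs and 6 for the interaction. Subsample 1 of biosample 7 alone gave 2787 in normal biosamples, 125 in pulldowns and 5 for the interaction, and subsample 2 alone 17 for the interaction. A pseudocount of 0.1 gave 13 for the interaction, robust estimation 590 in pulldowns, and a threshold of 0.1 gave 714 in pulldowns, 640 in inputs and 109 for the interaction, by its own construction. Where no construction is named, the cause was not tested. Removing the length and GC trend gave 3808, 3340, 380, 302 and 34, all within 1.5 times. Depth limits values under 0.0917 to 0.703 CPM, where 3 reads or fewer were counted.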

Other observations

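The list and gene tests below were chosen before the data were examined, apart from the permutation test of Rpl10a between treatments. The edgeR test, the Y-linked sums and the subsample weights were chosen after the data were seen.

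The 6 lists that follow did not pass against all other genes in TRAP against input, and their shares of lower genes are to be set against 3509 of 14214 genes lower in normal and 3264 lower in paclitaxel pulldowns. Of 20 cell cycle genes 4 fell in normal and 9 fell and 1 rose in paclitaxel pulldowns against input (4, and 9 and 1, adjusted over the list alone; camera adjusted p = 0.343 and 0.161), with Rrm2, a ribonucleotide reductase subunit, at -2.2 in normal biosamples. Of 20 interferon-stimulated genes 6 fell in normal, and 9 fell and 1 rose in paclitaxel biosamples (6, and 9 and 1, over the list alone; adjusted p = 0.811 and 0.239), with the RNA sensor gene Ifih1 at -2.23 and -2.54. Of 17 p53 target genes 7 fell and 2 rose, and 6 fell (9 and 2, and 6, over the list alone; adjusted p = 0.352 and 0.214), with Trp53inp1 at -2.73 and -1.55. Of 22 nerve injury response genes 7 fell in normal, and 4 fell and 2 rose in paclitaxel biosamples (7, and 4 and 2, over the list alone; adjusted p = 0.807 and 0.66), with the neurotrophin gene Bdnf at -1.5 in normal and the neuropeptide galanin gene Gal at 1.1 in paclitaxel biosamples. Of 14 axon maintenance genes 5 fell and 1 rose, and 2 fell and 2 rose (5 and 2, and 3 and 2, over the list alone; adjusted p = 0.755 and 0.198), with the kinase gene Map3k12 at -0.993 and -0.709. Of 5 oligodendrocyte and astrocyte markers 2 and 3 fell (3 and 5 over the list alone; adjusted p = 0.44 and 0.0528), with Gfap at -1.46 and -2.05.

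Of 24 cholesterol and fatty acid synthesis genes 2 rose and 8 fell in normal and 3 rose and 3 fell in paclitaxel pulldowns against input (the same numbers over the list alone; camera adjusted p = 0.594 and 0.0192, the latter adjusted p = 0.0866 with an estimated correlation, 0.686 under quantile normalization and 0.614 with fry, with a median of 0.063 and a mean of -0.0022), with Mvd of the mevalonate pathway at 1.52 and 0.691. Of 16 heat shock genes 3 rose and 5 fell, and 4 rose and 2 fell (4 and 5, and 5 and 5, over the list alone; adjusted p = 0.0916 and 0.00932, the latter adjusted p = 0.0866 with an estimated correlation, 0.673 under quantile normalization and 0.372 with fry), with Hsp90aa1 at 1.49 and 0.987 and Cryab at -2.11 and -1.74. Of 24 unfolded protein and integrated stress response genes 4 rose and 6 fell, and 2 rose and 4 fell (5 and 8, and 2 and 4, over the list alone; adjusted p = 0.0916 and 0.161), with the chaperone gene Calr at 1.37 in normal biosamples. Of 55 pain-related ion channels 7 rose and 15 fell in normal pulldowns (7 and 16 over the list alone, adjusted p = 0.352), with Scn3a at -2.87. For the stress response, axon, cholesterol, heat shock and ion channel lists of normal biosamples the test pointed upward while the median and the mean were below 0. In paclitaxel against normal pulldowns Hspa8, a constitutive chaperone, rose by 1.74, Ifi27 by 1.4, the channel gene Ano3 by 1.19, and Cenpf, a mitotic kinetochore gene, by 3.15; Cenpf also rose by 2.09 and Phlda3, a p53 target, by 1.29 in the inputs.

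Rpl10a, the gene of the endogenous counterpart of the tagged protein, had 11.5 ± 7.61 CPM in normal input, 8.31 ± 5.31 in normal TRAP, 22.7 ± 7.03 in paclitaxel input and 61.3 ± 42.0 in paclitaxel TRAP (SD, n = 4); it was higher in TRAP in 6 of 8 biosamples (mean log2 difference 0.4 ± 1.62, exact sign-flip p = 0.516). Between treatments it differed by 2.84 in the pulldowns (exact permutation p = 0.0286, adjusted p = 0.153). Esm1, an endothelial gene, was lower in TRAP by -1.54 in normal and -1.81 in paclitaxel biosamples (limma adjusted p = 0.0423 and 0.0204), with inputs of 3.38 and 4.36 CPM, and neither value passed under quantile normalization (adjusted p = 0.628 and 0.651) or by edgeR (0.264 and 0.19), nor the normal one under median-ratio scaling (0.0823).

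The subsamples of biosample 7 correlated across genes at r = 0.96 in input and r = 0.77 in TRAP, and genes are not independent replicates. The TRAP value lay below the r = 0.83 to 0.91 between paclitaxel TRAP libraries of different biosamples, computed after the subsamples were averaged. The authors' merged columns weight subsample 1 by 0.368 in input and 0.258 in TRAP. The deviations of the input and the pulldown of 1 biosample from their group means correlated across genes at r = 0.053, 0.15, 0.21, 0.38, 0.13, 0.2, 0.17 and 0.19 for biosamples 1 to 8, and those of different biosamples at r = -0.32 to 0.16. The summed CPM of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty was 170, 48.7, 98.3 and 218 in normal inputs and 105, 60.7, 97.6 and 62.4 in paclitaxel inputs, and 14.3, 11.2, 53, 135, 20.8, 19.6, 73.1 and 33.4 in the pulldowns of biosamples 1 to 8.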
